A study of Arabidopsis thaliana with 36 samples.

How the data were processed

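The deposited data were 7 tables of read counts per gene over the same 36 RNA-seq libraries, which covered 2 accessions of Arabidopsis thaliana in 6 conditions and 3 independent experiments. Per the labels' protocols, each library was made from RNA of a pool of 5 replicate samples of rosettes, with polyA enrichment and a directional kit that keeps the strand of the RNA. The reads had been mapped or assigned to the TAIR10 build, per the submitters' processing notes, which name BWA 0.7.13, RSEM 1.2.30, STAR 2.5.2a, TopHat2 2.1.1, kallisto 0.42.5, Salmon 0.6.0, SAMtools 1.3 and HTSeq 0.7.2. Which of these tools used the strand is not given in the sources used here. The STAR, TopHat, BWA and CLC tables held whole-number counts as deposited by the authors, with no normalization. The kallisto, RSEM and Salmon tables held expected counts as deposited by the authors, of which 86.6%, 94.2% and 86.8% were whole numbers, and these were rounded to whole numbers before use. The BWA table held the same block of values in 2 copies, and the first copy was read. Columns were tied to libraries through the column letter that the labels give for each library.

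Total counts per library in the STAR table ran from about 17861500 to 31046200, from 19296700 in Col-0 and up to 29917800 in N14. The most abundant gene took between 1.70% and 3.56% of the counts of a library, and organelle genes between 0.296% and 0.708%. No pair of replicates agreed within sampling noise, since the chi-square per gene between replicates of a group ran from 8.42 to 106 over 36 pairs, so each library was counted once. A floor of 3 counts per library was kept, and no fold is given for a gene at or under it in both groups. Gene symbols came from the TAIR10.1 reference annotation, which held 32835 of the 33602 identifiers, and no coordinates are given because that assembly is not the build of the tables.

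The STAR counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 20263, libraries were scaled with TMM, and the quasi-likelihood model was fitted to all 36 libraries with a mean for each of the 12 groups, so that the groups shared an estimate of the spread. Each comparison was a contrast of group means, tested with the quasi-likelihood F test and adjusted by the Benjamini-Hochberg method over the genes of that contrast, and a gene was called at an adjusted p under 0.05. The number of called genes that differed by at least 2-fold is given beside the count. Changes are log2 fold changes ± SE, where the SE is the change divided by the square root of F, and levels are counts scaled to library size (CPM, as edgeR defines it) with TMM scaling, as mean ± SD over the 3 libraries of a group. Log2 CPM used a prior count of 2. With 3 libraries against 3, the values of 2 groups fail to overlap by chance in 10% of genes, and non-overlap was used only to choose genes to name.

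Before the data were examined, 19 gene lists with 254 members were fixed: CBF transcription factors (with regulators of the CBF genes and other cold-induced factors), cold-regulated (COR) effectors, ABA response, flavonoid and anthocyanin synthesis, starch, sugar and proline metabolism, light-harvesting and Rubisco small subunits, early light-induced and photoprotection, lipid desaturation and membrane lipids, lipid transfer proteins, reactive oxygen detoxification, jasmonate synthesis and response, salicylate-dependent defence, cell wall expansion, circadian clock, heat shock proteins, flowering regulators, leaf senescence, and floral organ and root markers as signs of other tissue. Of the members, 243 were tested. Lists were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 19 lists of a contrast, and again with an estimated correlation. Counts of called members are given over all genes tested and adjusted over the list alone. Under the estimated correlation the list calls that held were the floral organ markers, flowering regulators and lipid transfer proteins with age in Col-0, the jasmonate and lipid transfer lists with age in N14, the flowering and floral lists between triggered accessions, and the floral list in the difference of accessions with age.

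The rule for named genes was also fixed before the data were examined. It took 10 genes in every contrast they were described for (COR15A, CBF1, CBF2, CBF3, CHS, ELIP1, PR1, VSP2, LTP4 and FLC), up to 4 members of each described list with the largest change among the called (the largest of all where none was called), and the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, a condition dropped for differences between accessions in a response. The smallest changes were left out where a contrast would name more than about 30 genes.

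Of the 18 contrasts, 17 were fixed before the data were examined and the difference between accessions in the change with age was added afterwards. Each was refitted with the TopHat, BWA, CLC, kallisto, RSEM and Salmon tables, with no filter on low counts, with size factors of the relative log expression method in place of TMM, with DESeq2 1.42.0, with the libraries of the compared groups alone, with the experiment number as a block, and without each library in turn. A fit with a block for each pair of Col-0 and N14 pools of the same condition and experiment was added after the data had been seen. The replicate numbers mark 3 independent experiments, per the series' design. Residuals of libraries with the same number correlated by a mean of 0.06 between conditions (range -0.36 to 0.46, against -0.03 for different numbers) and by 0.38 between the Col-0 and N14 pools of a condition (range 0.07 to 0.65), so the numbers paired the accessions within a condition more than the conditions. Between the 28-day controls of the accessions 1 of the 3 pairs stood at 0.07. Between conditions the 3 pairs of the same number all exceeded 0.1 in the first cold at 35 days of Col-0 alone, at 0.16, 0.23 and 0.13.

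The fit was tested on simulated counts with 200 changed genes among 20188. In the simulated memory contrast of Col-0 the test recovered 10%, 50%, 88% and 96% of genes changed 1.5-, 2-, 4- and 8-fold. The same figures were 8%, 48%, 82% and 86% for second against first cold in N14, 10%, 48%, 88% and 94% for age in N14, and 2%, 24%, 78% and 90% for the difference between accessions in priming. Unchanged genes made up 1.75% to 7.46% of the calls over these 4 simulations, and between 10.9% and 15.6% of the calls of DESeq2 on the same counts with 20263 genes. The simulated counts were drawn independently for each gene and library around the group means. They lacked the structure by experiment that the real libraries showed, so these shares may not hold for the real contrasts.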

Results

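RNA was sequenced from rosettes of 2 accessions of Arabidopsis thaliana, the reference accession Col-0, of intermediate freezing tolerance, and the cold-tolerant accession N14. Each accession was sampled in 6 conditions and 3 independent experiments, which gave 36 libraries in 12 groups of 3. The conditions were 28-day control plants, plants primed with 3 days at 4 °C, primed plants after a lag of 7 days at 20 °C, plants triggered with a further 3 days at 4 °C after that lag, 35-day control plants and plants given their first 3 days of cold at 35 days. Cold was given under 90 µE of light and the 28-day plants had grown under 200 µE, so that temperature and light changed together. The labels give 15 rosettes for the 28-day control and the primed groups and 4 for the later groups, and 5 replicate samples for each pool. Whether rosettes were counted per replicate sample or per pool is not settled here. Plants sampled after the lag were 3 days older than the 35-day controls they were compared with. Cold-treated plants were likewise 3 days older than their controls, or than the lag plants in the case of triggering. Triggered plants were also 3 days older than plants after the first cold at 35 days. Total counts per library ran from about 17861500 to 31046200, and 20263 genes had enough counts to be tested. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, each group having 3 libraries, and levels are CPM ± SD over those 3 libraries.

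Libraries from cold-treated plants separated from all others on the first principal component of log2 CPM, which held 41.6% of the variance, and the accessions separated on the second, with 28.8%. Cold-treated libraries lay between 28.7 and 101 on the first component and the others between -107 and -31.8.

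**Figure D1:**
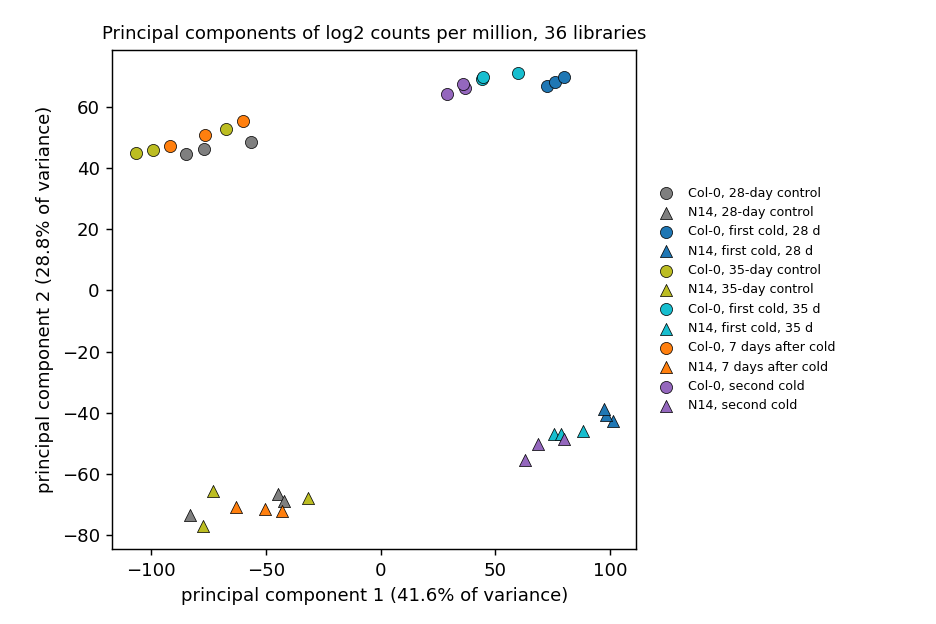
Scores of the 36 libraries on the first 2 principal components of log2 CPM, in which each point is a library, circles are Col-0, triangles are N14 and colours are conditions. Cold-treated libraries lie to the right of all others on the first component, which holds 41.6% of the variance, and Col-0 lies above N14 on the second, which holds 28.8%.

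Priming, the first 3 days of cold at 28 days, was examined for the genes that respond in Col-0. The early light-induced proteins ELIP1 [AT3G22840] and ELIP2 [AT4G14690], chlorophyll-binding proteins of the thylakoid, had among the largest rises, by 8.17 ± 0.63 and 7.65 ± 0.70 on the log2 scale. ELIP1 went from 5.65 ± 0.654 to 1637 ± 330 CPM. Of 15 COR effectors, many of them proteins that protect cells during freezing, 12 rose and none fell, led by KIN1 [AT5G15960] (6.92 ± 0.51), LTI30 [AT3G50970] (4.92 ± 0.40), COR15A [AT2G42540] (4.85 ± 0.44) and COR15B [AT2G42530] (4.30 ± 0.51). COR15A rose from 149 ± 60.0 to 4314 ± 843 CPM. All 21 tested genes of flavonoid and anthocyanin synthesis rose, with a median change of 4.53, among them F3PRIMEH [AT5G07990] (5.98 ± 0.59), UF3GT [AT5G54060] (5.57 ± 0.70), F3H [AT3G51240] (5.5 ± 0.49) and CHS [AT5G13930] (5.05 ± 0.49), which encodes chalcone synthase, the entry enzyme of the pathway.

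Genes of the photosynthetic apparatus fell in primed Col-0. Of 21 light-harvesting and Rubisco small subunit genes, 19 fell, with a median of -1.93, led by RBCS2B [AT5G38420] (-3.48 ± 0.25), RBCS3B [AT5G38410] (-3.32 ± 0.21), LHCB2.3 [AT3G27690] (-3.20 ± 0.42) and LHCB1.4 [AT2G34430] (-2.91 ± 0.42). In starch, sugar and proline metabolism 9 of 19 genes rose and 4 fell. The raffinose synthase gene RS6 [AT5G20250] changed by -4.90 ± 0.89, the sucrose synthase gene SUS1 [AT5G20830] by 3.96 ± 0.28, the beta-amylase gene BAM3 [AT4G17090] by 3.35 ± 0.33 and the debranching enzyme gene ISA3 [AT4G09020] by 3.10 ± 0.29. In the circadian clock list 5 of 13 genes rose and none fell, with LHY [AT1G01060] at 4.87 ± 0.30 (3.63 ± 1.38 to 107 ± 2.65 CPM), CCA1 [AT2G46830] at 2.78 ± 0.45 and GI [AT1G22770] at 2.07 ± 0.29. Outside the lists, the glucose-6-phosphate transporter gene GPT2 [AT1G61800] rose by 6.51 ± 0.64. The expansin gene EXPA8 [AT2G40610] changed by -6.93 ± 0.55 from 138 ± 20.9 CPM, the senescence-associated gene SEN1 [AT4G35770] by -7.47 ± 1.19, AT4G27450 by -7.42 ± 0.99, the gibberellin-regulated gene GASA6 [AT1G74670] by -6.55 ± 0.69 and the xylosidase gene BXL1 [AT5G49360] by -6.52 ± 0.73, the largest falls.

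The remaining lists moved less as groups in primed Col-0. The CBF list, which held CBF genes and their regulators together with other cold-induced transcription factors, had 1 of 10 genes higher and 1 lower after 3 days, the regulators HOS1 [AT2G39810] (0.88 ± 0.19) and ICE2 [AT1G12860] (-1.18 ± 0.15). CBF1 [AT4G25490], CBF2 [AT4G25470] and CBF3 [AT4G25480] themselves, a tandem array of factors that switch on COR genes, stood at -0.85, -0.04 and -0.30, none of them called. The value of CBF3 depended on the primed pool of experiment 1, at 15.1 CPM against 3.77 and 3.66 in the others, and was -1.31 without it (adjusted p = 0.089). Of 16 salicylate-dependent defence genes 7 rose and none fell, with PR1 [AT2G14610] at 3.64 ± 1.3 (adjusted p = 0.019), PR5 [AT1G75040] at 2.70 ± 0.53 and PR2 [AT3G57260] at 2.23. PR1 varied between pools (35.7 ± 42.2 against 2.84 ± 1.77 CPM), and its call ended without the primed pool of experiment 1 (1.99 for PR1 in priming Col-0) or the control pool of experiment 2 or 3. Of 13 jasmonate genes 1 rose, JAZ1 [AT1G19180] (1.75 ± 0.54, a call that ended without the primed pool of experiment 2), and 4 fell, among them VSP2 [AT5G24770], a vegetative storage protein induced by jasmonate (-3.47 ± 0.67, adjusted p = 9.0e-05). The lipid transfer list had 2 genes higher and 2 lower of 10, led by AZI1 [AT4G12470] (6.16 ± 0.66) and EARLI1 [AT4G12480] (5.11 ± 0.56), with LTP4 [AT5G59310] at -0.22 and not called. The floral repressor FLC [AT5G10140] fell by 0.72 ± 0.26 (adjusted p = 0.019) from a low level of 5.57 ± 1.82 CPM, a call that ended without the control pool of experiment 2 or 3 or the primed pool of experiment 2.

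Among the other lists, higher and lower members in primed Col-0 numbered 3 and 0 of 15 for ABA response, 2 and 5 of 10 for early light-induced and photoprotection, 3 and 3 of 11 for lipid desaturation (with ADS1 at -4.78 ± 0.49 and FAD8 at 1.05 ± 0.31), 5 and 4 of 14 for reactive oxygen detoxification, and 1 and 7 of 17 for cell wall expansion. They numbered 0 and 1 of 7 for heat shock proteins, 1 and 5 of 13 for flowering regulators, 0 and 5 of 10 for leaf senescence, 0 and 0 of 6 for floral organ markers and 0 and 1 of 2 for root markers. Adjusted over the list alone, the counts that differed were 10 and 4 for the starch list, 2 and 0 for ABA response, 1 and 3 for the jasmonate list, 0 and 0 for heat shock and 0 and 3 for senescence. The early light-induced list had a median of -0.35 but a mean of 1.25 and an upward test direction, which ELIP1 and ELIP2 set, and the lipid transfer list a median of -0.18, a mean of 0.80 and an upward direction. The CBF list had a median of 0.06 and a mean of 0.22 and a downward direction. In the other 5 cold comparisons the median of the early light-induced list and that of the lipid transfer list were also negative and the mean positive, and no list past camera's test in any comparison had a median, mean and direction of different sign.

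Priming of Col-0 called 11082 genes, 5401 higher and 5681 lower, of which 2433 and 3097 differed by at least 2-fold. By camera, the flavonoid (adjusted p = 2.1e-13), COR (1.7e-06), starch (0.010) and clock (0.045) lists were higher and the light-harvesting list was lower (1.6e-12). With an estimated correlation none of these calls held, and the adjusted p was 0.30 for the flavonoid, 0.41 for the COR, 0.50 for the starch, 0.45 for the clock and 0.41 for the light-harvesting list. Reads of KIN1 and its near copy KIN2 [AT5G15970], COR15A and COR15B, ELIP1 and ELIP2, and the members of the LHCB and RBCS families can be split between copies by the counting, so the change of a single member is uncertain.

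**Figure D2:**
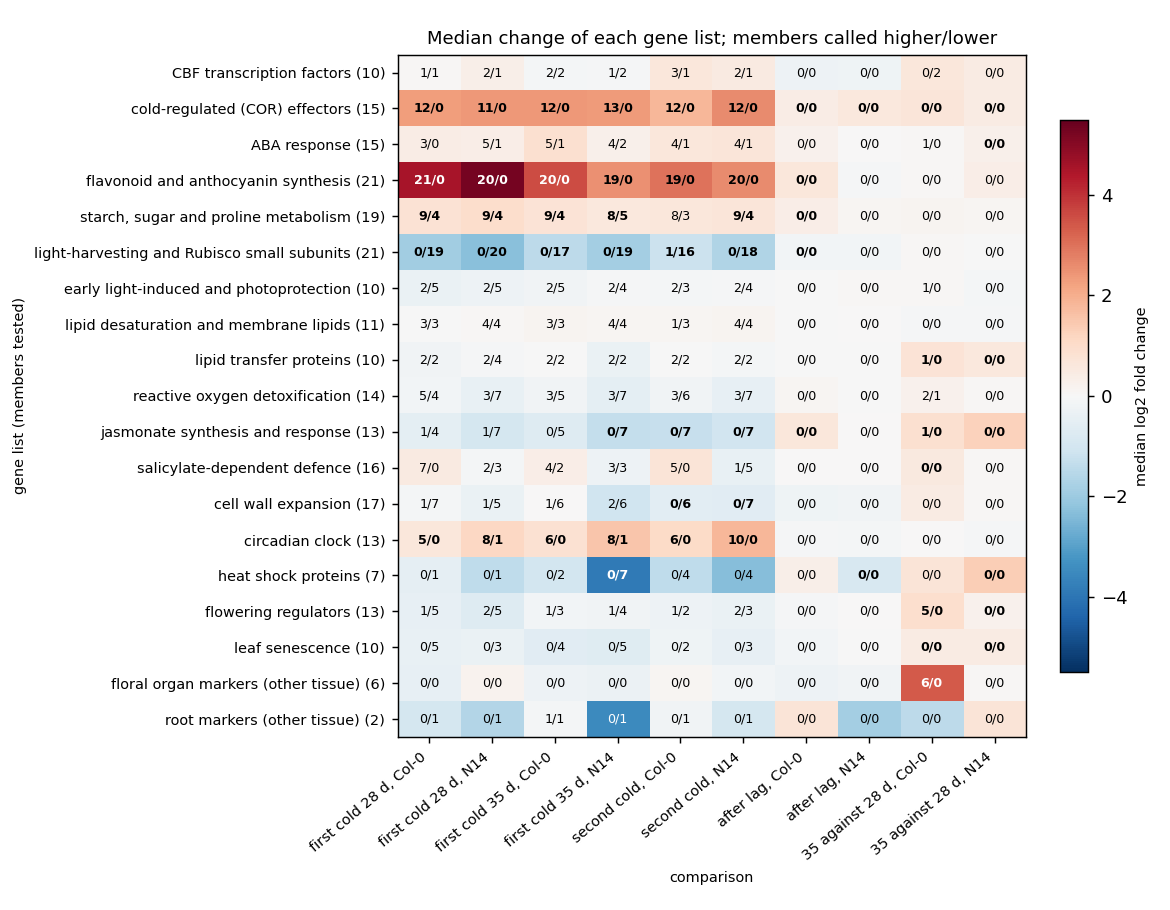
Median log2 fold change of the tested members of each of the 19 gene lists (rows, with the number tested) in 10 comparisons (columns), as colour, with the number of members called higher and lower in each cell. Bold marks lists past camera's test at its preset correlation; the flavonoid list rises and the light-harvesting list falls in all 6 cold comparisons, with 21 flavonoid members called higher and 19 light-harvesting members called lower in primed Col-0.

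Priming of N14 was examined for the same genes and lists. ELIP2 and ELIP1 rose by 8.53 ± 0.73 and 7.97 ± 0.63, the latter from 6.74 ± 2.22 to 1681 ± 571 CPM. Of the 15 COR effectors 11 rose and none fell, with LTI30 at 4.86 ± 0.40, COR27 [AT5G42900] at 4.49 ± 0.79, COR15A at 4.08 ± 0.43 (285 ± 155 to 4830 ± 520 CPM) and KIN1 at 3.99 ± 0.44. Of 21 flavonoid genes 20 rose, and 21 adjusted over the list alone, with F3PRIMEH at 6.11 ± 0.61, LDOX [AT4G22880], an anthocyanidin synthase gene, at 6.03 ± 0.80 and CHS at 5.28 ± 0.49. Of the light-harvesting and Rubisco genes 20 fell, with LHCB2.3 at -4.08 ± 0.44 and RBCS2B at -3.79 ± 0.26. In the clock list 8 rose and 1 fell (9 and 1 adjusted over the list alone), with LHY at 3.93 ± 0.28, ELF4 [AT2G40080] at 3.00 ± 0.49, GI at 2.54 and CCA1 at 2.50. In the starch list 9 rose and 4 fell, with ISA3 at 3.83, SUS1 at 3.57, BAM3 at 3.31 and RS6 at -4.69. GPT2 rose by 5.88 ± 0.62, SEN1 changed by -7.56, AT4G27450 by -7.41, EXPA8 by -7.31 ± 0.54, GASA6 by -7.10 and the chaperone gene J8 [AT1G80920] by -6.26.

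FLC fell in primed N14 by 1.02 ± 0.23, from 152 ± 29.97 to 74.9 ± 2.12 CPM. Of 13 jasmonate genes 7 fell and 1 rose, led by the allene oxide cyclase gene AOC1 [AT3G25760] at -2.41 ± 0.31. VSP2 fell by 1.48 ± 0.62 (adjusted p = 0.043), and that call ended without any of 4 of the 6 pools (changes from -1.44 to -1.25 for VSP2 in priming N14). PR1 stood at 0.99 and was not called, and CBF1, CBF2 and CBF3 stood at -1.18, -0.28 and 0.39, none called. CBF3 in priming N14 was -0.55 without the primed pool of experiment 1, which stood at 26.3 CPM against 6.22 and 7.66. Priming of N14 called 11501 genes, 5584 higher and 5917 lower (2573 and 3338 by at least 2-fold). By camera the flavonoid (adjusted p = 4.4e-12), COR (1.1e-04), clock (0.0066) and starch (0.022) lists were higher and the light-harvesting list lower (1.8e-13). The adjusted p with an estimated correlation was 0.24, 0.57, 0.24, 0.65 and 0.24 in the same order.

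Both accessions shared 4556 genes that rose and 4688 that fell with priming, against 1488 and 1659 for independent lists, and 19 genes went opposite ways. The changes correlated by 0.87 across genes, which are not independent replicates. No control library was shared between these comparisons.

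**Figure D3:**
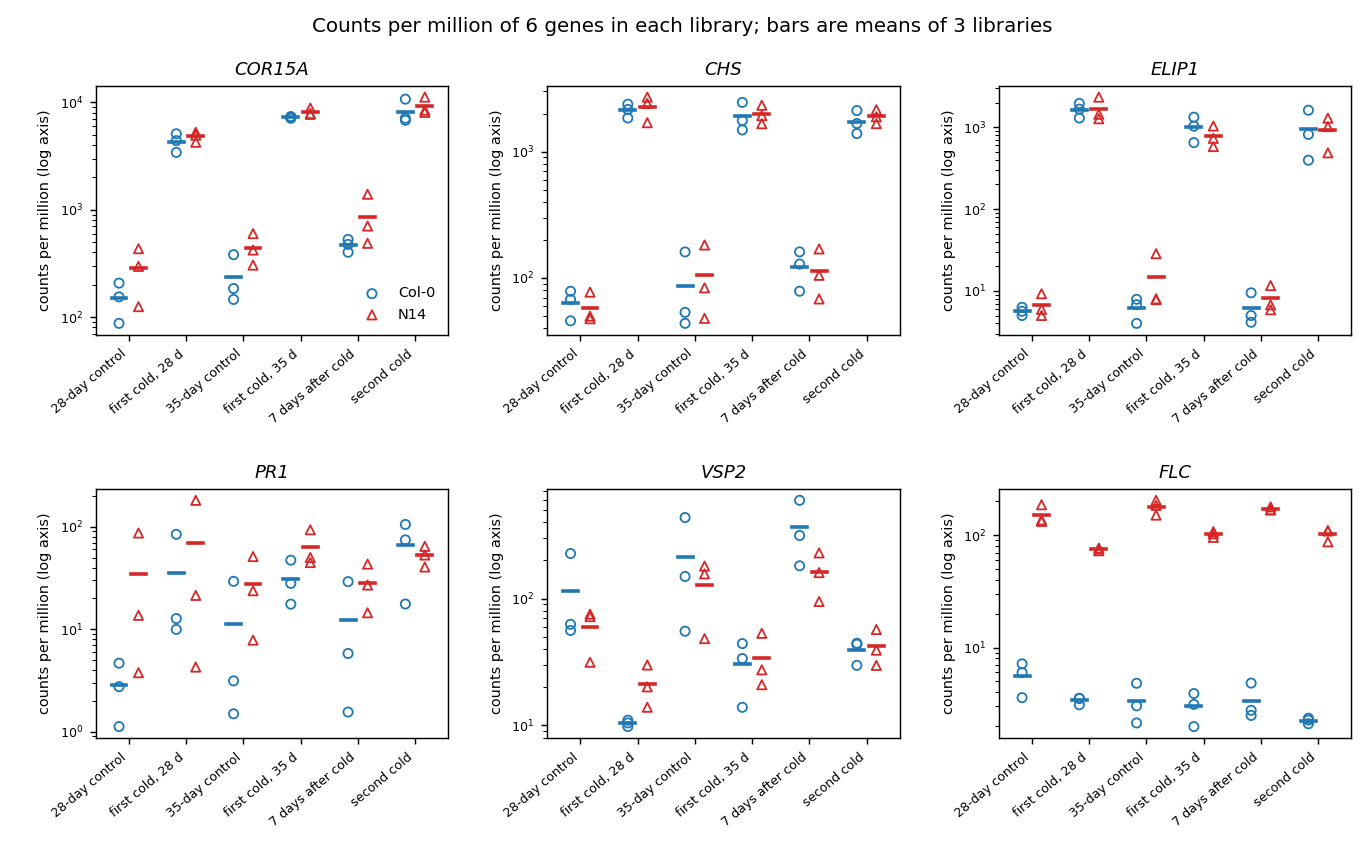
CPM on a log axis of COR15A, CHS, ELIP1, PR1, VSP2 and FLC in each of the 36 libraries by condition, with circles for Col-0, triangles for N14 and bars for the mean of 3 libraries. COR15A, CHS and ELIP1 lie higher in all cold-treated pools than in the others (ELIP1 in Col-0 at 5.65 CPM before and 1637 CPM after priming), while PR1 spreads widely inside groups and FLC stays higher in N14.

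A first cold treatment at 35 days served as the developmental counterpart of priming. In Col-0 the largest rises were ELIP1 (7.33 ± 0.61), ELIP2 (7.14), KIN1 (6.85 ± 0.50), AZI1 (5.56) and LTI30 (5.46 ± 0.41). COR15A rose by 4.94 ± 0.44, from 237 ± 126 to 7266 ± 138 CPM, and 12 of 15 COR effectors rose, GOLS3 [AT1G09350], a galactinol synthase gene, at 4.59. Of 21 flavonoid genes 20 rose (21 adjusted over the list alone), with the glutathione transferase gene TT19 [AT5G17220] at 5.01 ± 0.52, F3H at 4.79 and CHS at 4.47 ± 0.47. Of the light-harvesting and Rubisco genes 17 fell, with RBCS2B at -3.70, and in the clock list 6 rose with LHY at 4.33. Of 13 jasmonate genes 5 fell, VSP2 among them at -2.81 ± 0.65 (-1.75 for VSP2 in first cold at 35 days Col-0 without the control pool of experiment 1), and the list did not pass camera's test. AT4G27450 (-7.38), SEN1 (-6.93), EXPA8 (-6.38), J8 (-5.75) and BXL1 (-5.72) fell most. CBF1, CBF2, CBF3, PR1 and FLC were not called.

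In N14 the first cold at 35 days raised ELIP1 (5.72 ± 0.56), LTI30 (5.55 ± 0.41), AT4G16563 (5.51), AT1G16850 (5.28) and ELIP2 (5.12) most. COR15A rose by 4.21 ± 0.43, from 442 ± 148 to 8170 ± 616 CPM, and COR27 by 5.00, among 13 of 15 COR effectors. CHS rose by 4.24 ± 0.47 among 19 of 21 flavonoid genes. RBCS2B changed by -4.07 among 19 light-harvesting and Rubisco genes that fell, and LHY (3.47) and CCA1 (3.02) rose among 8 clock genes, with 1 lower (2 adjusted over the list alone). All 7 tested heat shock genes fell, with a median of -3.88, HSP70 [AT3G12580] from 48.2 ± 47.4 to 2.85 ± 0.19 CPM (-4.08 ± 0.81) and HSP90.1 [AT5G52640] by -3.88 ± 0.74. The 35-day control pools of N14 differed widely in HSP70, at 99.8, 6.76 and 38.0 CPM, and without the pool of experiment 1 the number of heat shock genes that fell was 5. That pool also had the highest median of the 36 libraries over the 2 root markers tested, at 2.93 log2 CPM. Its PYK10 level was 85.1 CPM, against 16.3 and 19.2 in the other 35-day N14 pools and 133 in the 28-day Col-0 pool of experiment 1. Heat shock and root markers were thus high together in this 35-day pool. The N14 lag pool of experiment 1 had a higher heat shock median (2.89 against 2.45 log2 CPM) with a root median of 0.07. Of 13 jasmonate genes 7 fell, with AOC1 at -2.54 and VSP2 at -1.92. SEN1 (-7.32), AT4G27450 (-7.21), EXPA8 (-6.26), J8 (-5.79) and AT5G19120 (-5.51) fell most, CBF1 fell by 2.69 ± 0.79 (adjusted p = 0.0052) and FLC by 0.82 ± 0.23.

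The first cold at 35 days called 10503 genes in Col-0, 5402 higher and 5101 lower (2431 and 2800 by at least 2-fold), and 10946 in N14, 5070 higher and 5876 lower (2160 and 3383). In Col-0 camera's adjusted p was 1.5e-07 for the COR, 6.7e-11 for the flavonoid, 0.033 for the starch, 2.1e-09 for the light-harvesting and 0.024 for the clock list, and with an estimated correlation the adjusted p was 0.40, 0.40, 0.73, 0.40 and 0.40. In N14 it was 6.3e-07 for the COR, 1.2e-07 for the flavonoid, 0.038 for the starch, 8.6e-11 for the light-harvesting, 0.0012 for the clock, 0.026 for the heat shock and 0.043 for the jasmonate list. With an estimated correlation the adjusted p in N14 was 0.32 for the COR, flavonoid, light-harvesting and clock lists and 0.55 for the starch, heat shock and jasmonate lists. Without the 35-day control pool of experiment 1 camera's adjusted p was 0.079 for both the heat shock and the jasmonate list of N14. Of the genes called at both ages, 4502 rose and 4449 fell in Col-0 (1440 and 1430 for independent lists) with none opposite, and 4445 rose and 4790 fell in N14 with 6 opposite.

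Triggering, the second cold treatment, was compared with plants at the end of the lag. In Col-0 ELIP1 (7.24 ± 0.61), ELIP2 (6.58), KIN1 (6.22 ± 0.49), AZI1 (5.72) and LTI30 (5.29 ± 0.40) rose most. COR15A rose by 4.13 ± 0.43, from 469 ± 64.1 to 8229 ± 2180 CPM, with 12 of 15 COR effectors higher and GOLS3 at 4.71. Of the flavonoid genes 19 rose (20 adjusted over the list alone), with TT19 at 4.15, UF3GT at 4.01 and CHS at 3.81 ± 0.46. Of the light-harvesting and Rubisco genes 16 fell and 1 rose, with RBCS2B at -3.68, and in the clock list 6 rose with LHY at 4.18 and CCA1 at 2.93. Jasmonate genes fell in 7 of 13 cases, with VSP2 at -3.21 ± 0.66, AOC1 at -1.75 and MYC2 [AT1G32640], a regulator of jasmonate responses, at -1.54. Cell wall expansion genes fell in 6 of 17 cases, with EXPA1 [AT1G69530] at -2.19. CBF2 rose by 1.37 ± 0.52 (adjusted p = 0.038), a call that ended without the lag pool of experiment 1 or 3 or the triggered pool of experiment 3 (0.67 for CBF2 in triggering Col-0 without the last). AT4G27450 (-5.52), EXPA8 (-4.99), BXL1 (-4.96), SEN1 (-4.87) and GASA6 (-4.50) fell most.

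In N14 triggering raised ELIP1 (6.84 ± 0.60), ELIP2 (6.83), LTI30 (5.22), AT1G16850 (5.03) and COR27 (4.83) most. COR15A rose by 3.42 ± 0.41, from 862 ± 475 to 9255 ± 1714 CPM, among 12 COR effectors (13 adjusted over the list alone). CHS (4.05 ± 0.46) and F3H (3.94) rose among 20 flavonoid genes, and LHY (3.81), CCA1 (3.05), PRR5 [AT5G24470] (3.01) and ELF4 (2.57) among 10 of 13 clock genes. RBCS2B changed by -3.95 among 18 light-harvesting and Rubisco genes that fell. VSP2 (-1.94) and AOC1 (-1.88) fell among 7 jasmonate genes, and 7 cell wall genes fell. FLC fell by 0.75 ± 0.23, and CBF1, CBF2 and CBF3 were not called. AT4G27450 (-5.96), SEN1 (-5.75), RS6 (-5.33), AT5G19120 (-5.23) and GASA6 (-5.11) fell most.

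Triggering called 8149 genes in Col-0, 4367 higher and 3782 lower (1550 and 1983 by at least 2-fold), and 9450 in N14, 4539 higher and 4911 lower (1626 and 2538). In Col-0 camera's adjusted p was 8.1e-08 for the COR, 1.6e-10 for the flavonoid, 5.9e-10 for the light-harvesting, 0.011 for the jasmonate, 0.034 for the cell wall and 0.0050 for the clock list, and with an estimated correlation the adjusted p was 0.27, 0.27, 0.36, 0.45, 0.45 and 0.27. In N14 it was 1.7e-06, 2.2e-09, 3.0e-11, 0.028, 0.025 and 8.4e-05 for the same lists and 0.025 for the starch list. With an estimated correlation the adjusted p in N14 was 0.31 for the COR, flavonoid and light-harvesting lists, 0.55 for the jasmonate and starch lists, 0.46 for the cell wall list and 0.13 for the clock list. Of the genes called in the first cold at 35 days and in triggering, 3904 rose and 3369 fell in Col-0 with 1 opposite, and 3983 rose and 4236 fell in N14 with 2 opposite.

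Plants after the lag were compared with 35-day controls to ask what remained of the first cold. In Col-0 no gene passed edgeR's adjusted test, 670 genes had an unadjusted p under 0.05, and DESeq2 called 4 genes. COR15A stood at 469 ± 64.1 CPM after the lag and 237 ± 126 in the controls (0.98 ± 0.38, adjusted p = 0.98), and RD29A [AT5G52310], a COR effector, differed by 1.05 ± 0.39. In N14 the count was also 0, with 919 genes at an unadjusted p under 0.05 and 61 called by DESeq2, 3 higher and 58 lower. COR15A stood at 862 ± 475 and 442 ± 148 CPM in N14 (0.97 ± 0.38, adjusted p = 0.80).

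As groups, the COR list lay higher after the lag in both accessions, with medians of 0.43 in Col-0 (adjusted p = 5.2e-06 by camera) and 0.57 in N14 (1.5e-06), and with an estimated correlation the adjusted p was 0.34 and 0.44. In Col-0 the flavonoid list (median 0.61, 3.4e-07), the starch list (0.37, 1.4e-04) and the jasmonate list (0.63, 1.6e-05) lay higher, and the light-harvesting list lay lower (-0.14, 0.016). By experiment the median of the flavonoid list in Col-0 was 1.48, 0.84 and -0.32, so that its direction turned in experiment 3, while that of the COR list was 0.14, 0.21 and 0.93 in Col-0 and 1.14, 0.23 and 0.59 in N14. With an estimated correlation the adjusted p was 0.34 for the first 3 and 0.74 for the light-harvesting list. Examples were the dihydroflavonol reductase gene DFR [AT5G42800] at 1.60 ± 0.71, CHS at 0.51, the lipoxygenase gene LOX2 [AT3G45140] at 1.08, AOC1 at 0.97 ± 0.30 and VSP2 at 0.77 ± 0.61, none called. In N14 the heat shock list lay lower (median -0.88, 1.6e-04, adjusted p = 0.44 with an estimated correlation), and without the 35-day control pool of experiment 1 its adjusted p was 0.25. Adjusted over the list alone, 2 jasmonate genes and 1 senescence gene were higher in Col-0 and 3 heat shock genes lower in N14. Leaving out 1 pool changed the counts: 1 gene was called in Col-0 without the lag pool of experiment 1, and in N14 the count reached 179 without the 35-day control pool of experiment 3 and 113 without that of experiment 2.

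The second cold was compared with a first cold given at 35 days to ask whether primed plants responded differently. In Col-0 no gene passed edgeR's adjusted test, 937 had an unadjusted p under 0.05 and DESeq2 called 3. COR15A reached 8229 ± 2180 CPM in the second cold and 7266 ± 138 in the first (0.18 ± 0.38), CHS differed by -0.14, CBF1 by 1.49 ± 0.76 and CBF3 by 1.04 ± 0.58, none called. No list passed camera's test in Col-0, the smallest adjusted p being 0.51. In N14 COR15A reached 9255 ± 1714 and 8170 ± 616 CPM (0.18 ± 0.38), CBF1 differed by 1.97 ± 0.78 (adjusted p = 0.37) and CBF3 by 1.57 ± 0.59 (adjusted p = 0.32). The called gene in N14 was AT1G14600, higher by 1.48 ± 0.24 (adjusted p = 0.015), named because it was the entire count and outside the rule for named genes. In N14 1765 genes had an unadjusted p under 0.05, DESeq2 called 213, and the fit with the experiment as a block called 5.

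Salicylate-dependent defence genes lay lower in the second cold of N14 (median -0.26, camera's adjusted p = 0.0078, 0.88 with an estimated correlation), with SARD1 [AT1G73805], a regulator of salicylate synthesis, at -1.84 ± 0.49 (adjusted p = 0.13) and the transcription factor gene WRKY70 [AT3G56400] at -1.70. The cell wall list also lay lower (median -1.0, adjusted p = 0.028, and 0.88 with an estimated correlation), with XTH33 [AT1G10550] at -3.70 ± 1.14 (adjusted p = 0.18). Adjusted over the list alone, 3 salicylate genes were lower, and 3 cell wall genes were higher and 5 lower. The count in N14 was 532 when the 6 libraries of the comparison were fitted alone, and it ranged from 0 to 177 without single pools, the highest without the triggered pool of experiment 2.

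Control plants of 35 and 28 days were compared for what changed with age. The number of rosettes also changed, at 4 and 15, so that age and this number cannot be separated. In Col-0 all 6 floral organ markers rose, with a median of 3.39, from below 1 CPM, such as SEP3 [AT1G24260] at 2.54 ± 0.48 (0.501 ± 0.102 to 2.92 ± 0.741 CPM). AP3 [AT3G54340] went from 0.0272 ± 0.0237 to 1.02 ± 0.456 CPM and PI [AT5G20240] from 0.0995 ± 0.112 to 1.94 ± 0.556 CPM, with a mean under 3 counts per library at 28 days, so that their fold is imprecise. Of 13 flowering regulators 5 rose, among them the meristem identity genes AP1 [AT1G69120] (0.0824 ± 0.0366 to 2.70 ± 0.527 CPM) and FUL [AT5G60910] (2.03 ± 0.23, 2.65 ± 0.771 to 10.9 ± 0.492 CPM), SPL3 [AT2G33810] (1.56 ± 0.34) and SPL5 [AT3G15270] (1.53). The plant defensin genes PDF1.2 [AT5G44420] (3.58 ± 0.60, 8.75 ± 2.83 to 105 ± 38.4 CPM), PDF1.2c [AT5G44430] (3.70 ± 0.95) and PDF1.3 [AT2G26010] (3.49 ± 0.76), near copies whose reads can be split, rose with AT2G34655 (2.24 ± 0.32) and PCR1 [AT1G14880] (2.05 ± 0.53). The plastid transcripts ATCG01110 (-2.11 ± 0.44), ATCG01120 (-1.59), ATCG00750 (-1.47) and ATCG00760 (-1.44) fell, together with DFL1 [AT5G54510], an auxin-conjugating enzyme gene (-1.86 ± 0.47). Plastid transcripts mostly lack polyA tails, and the libraries were polyA-enriched.

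By camera, 7 lists lay higher with age in Col-0, and 3 held with an estimated correlation: the floral list (adjusted p = 3.0e-13, 3.3e-05 with an estimated correlation), the flowering list (1.7e-06, 0.0060) and the lipid transfer list (8.6e-05, 0.0037), in which 1 gene was called and 7 adjusted over the list alone. The other 4 were the jasmonate (median 0.89), COR (0.68), salicylate (0.52) and senescence (0.45) lists, with adjusted p of 1.4e-05, 5.6e-04, 0.0030 and 0.028, and of 0.11, 0.45, 0.36 and 0.36 with an estimated correlation. Adjusted over the list alone, 7 flowering genes rose and 1 fell, and 4 jasmonate and 3 COR genes rose. The root marker PYK10 [AT3G09260] stood at 133, 47.1 and 75.7 CPM in the 28-day Col-0 pools of experiments 1 to 3 and at 27.2, 15.5 and 12.7 in the 35-day pools (54.5, 46.4 and 54.0 against 85.1, 16.3 and 19.2 in N14), so the content of other tissue is not known to be alike at both ages. The comparison of 35 with 28 days called 690 genes in Col-0, 270 higher and 420 lower (149 and 124 by at least 2-fold). The count fell to 62, 136 and 217 without the 28-day pool of experiment 1 and the 35-day pools of experiments 2 and 1, rose to 1479 without the 28-day pool of experiment 2, and was 22 with those 6 libraries alone and 1184 by DESeq2. Of the genes named above, AP1, AP3, FUL, PDF1.2 and AT2G34655 were called without any single pool, and the calls of the others ended without at least 1 pool, the 28-day pools of experiments 1 and 3 and the 35-day pools of experiments 1 and 2 most often.

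In N14 age called 4 genes, 3 higher and 1 lower, 12 with the experiment as a block and 139 by DESeq2, and 1875 genes had an unadjusted p under 0.05. Among them were AT1G80130 (1.35 ± 0.24, 9.65 ± 1.77 to 24.5 ± 4.72 CPM) and AT2G43620 (4.48 ± 0.83, adjusted p = 0.044), whose level of 67.2 ± 104 CPM at 35 days rested on the pool of experiment 1 (a change of 1.29 for AT2G43620 in age N14 without it). Neither was called in any of the other 6 tables. The jasmonate list lay higher (median 1.29, 11 of 13 genes higher adjusted over the list alone, camera's adjusted p = 2.7e-12, 0.017 with an estimated correlation), with JAZ1 at 1.78 ± 0.55 (adjusted p = 0.21). The lipid transfer list also lay higher (median 0.59, adjusted p = 0.0039, 0.041 with an estimated correlation), with LTP4 at 3.10 ± 0.73 (adjusted p = 0.089). Without the 35-day pool of experiment 1 the lipid transfer list had a median of 0.31 and camera's adjusted p with an estimated correlation was 0.063. That adjusted p was 0.036 for the jasmonate list without the same pool. Without the 28-day pool of experiment 1 it was 0.0085 for the lipid transfer list. The heat shock (median 1.37, 3.3e-05), COR (0.46, 4.4e-04), flowering (0.24, 0.0033), ABA (0.26, 0.010) and senescence (0.45, 0.013) lists were higher by camera, with adjusted p of 0.10, 0.40, 0.11, 0.40 and 0.27 with an estimated correlation. HSP70 stood at 2.41 ± 0.74 (adjusted p = 0.21) and FUL at 1.60 ± 0.33 (adjusted p = 0.054). The count ranged from 0 without the 35-day pool of experiment 1 to 359 without that of experiment 3.

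**Figure D4:**
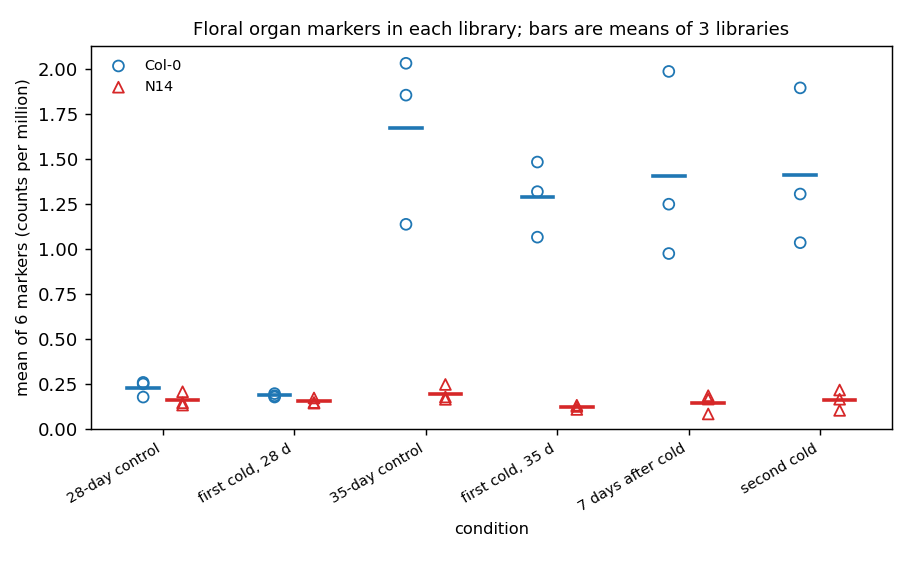
Mean CPM of the 6 floral organ markers in each library by condition, with circles for Col-0, triangles for N14 and bars for the mean of 3 libraries. The 12 Col-0 pools taken at 35 days or later lie at 0.974 CPM or above, while no pool of 28-day plants exceeds 0.259 CPM and no N14 pool exceeds 0.247 CPM.

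Untreated N14 and Col-0 plants of 28 days were compared to find differences between the accessions before cold. FLC was higher in N14 by 4.77 ± 0.28 (152 ± 29.97 against 5.57 ± 1.82 CPM, adjusted p = 9.3e-14), and the flowering activator SOC1 [AT2G45660], which FLC represses, was lower by a change of -4.04 ± 0.40 (3.76 ± 0.453 against 61.7 ± 13.2 CPM). Of 13 flowering regulators 1 was higher in N14 and 6 lower, MAF4 [AT5G65070] among them at -3.60. Among the largest changes were the epithiospecifier gene ESP [AT1G54040] at 6.35 ± 0.35 (3345 ± 939 against 41.0 ± 10.7 CPM), AOP2 [AT4G03060] at 5.53 ± 0.55 (688 ± 233 against 14.9 ± 9.24 CPM) and ESM1 [AT3G14210] at -4.30 ± 0.24 (39.2 ± 3.06 against 770 ± 151 CPM). AT2G36540 (8.54 ± 0.32), AT2G15555 (8.25 ± 0.66) and SADHU3-2 [AT3G42658] (5.60 ± 0.33) were also higher in N14. AT2G25450 (-7.91 ± 0.39, 0.933 ± 0.392 against 221 ± 54.7 CPM), TIR [AT1G72930] (-6.36), AT3G62530 (-5.94) and PCC1 [AT3G22231] (-5.93 ± 0.57) were lower. COR15A differed by 0.93 ± 0.38 and was not called (adjusted p = 0.12), and KIN1, at 1.76 ± 0.42 here, was lower in N14 in the CLC, kallisto and Salmon tables. In the BWA table PCC1 in accession naive differed by -1.03 and was not called.

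The naive accessions differed in 2501 genes, 1220 higher and 1281 lower in N14 (670 and 804 by at least 2-fold), in 1268 when those 6 libraries were fitted alone and in 4377 with a block for each pair of Col-0 and N14 pools. The salicylate list lay higher in N14 (median 0.86, camera's adjusted p = 0.0052, 0.79 with an estimated correlation), with PR2 at 2.59 ± 0.65 and PAD4 [AT3G52430] at 1.18 ± 0.25 called and 6 genes adjusted over the list alone. The median log2 CPM of the salicylate list was at least 3.13 in each N14 pool and at most 2.56 in each Col-0 pool. Without the N14 pool of experiment 1 the salicylate list had a median difference of 0.44 and an adjusted p of 0.19, and the PR2 call ended. PR1 stood at 86.8 CPM in that pool against 3.76 and 13.7 in the others, and the PAD4 call ended in every other table but TopHat. The flowering list lay lower (median -1.31, adjusted p = 0.0052, 0.30 with an estimated correlation), and of 21 flavonoid genes 3 were lower, or 7 adjusted over the list alone. With the pair block the flavonoid list passed camera's test as well (median -0.76, adjusted p = 0.027, 0.90 with an estimated correlation).

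Triggered plants of the accessions were compared in the same way. FLC was higher in N14 by 5.51 ± 0.29 (102 ± 12.8 against 2.23 ± 0.128 CPM), with AT2G15555 (8.05), AT2G36540 (7.53), ESP (5.87) and AT1G62290 (5.38). PCC1, a gene named for pathogen and circadian control, was lower by a change of -9.20 ± 0.64 (1.04 ± 0.263 against 610 ± 262 CPM), with AT2G25450 (-8.26), AT3G62530 (-6.74), TIR (-6.28) and the homeobox gene HB16 [AT4G40060] (-4.87). Of 21 flavonoid genes 10 were lower in N14 and 1 higher (11 and 1 adjusted over the list alone), led by the anthocyanin regulator PAP1 [AT1G56650] (-4.36 ± 0.80), DFR (-3.06 ± 0.69) and UF3GT (-2.95). In the lipid transfer list LTP5 [AT3G51600] (-1.75 ± 0.29) and LTP6 [AT3G08770] (-1.61) were among 4 lower genes and EARLI1 (1.52) was higher, or 6 lower and 2 higher adjusted over the list alone. All 6 floral organ markers were lower in N14, with SEP3 at -4.19 ± 0.55, and of the flowering regulators 8 were lower and 1 higher. COR15A differed by 0.17 ± 0.38 and was not called (adjusted p = 0.84).

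The triggered accessions differed in 2827 genes, 1170 higher and 1657 lower in N14 (588 and 1120 by at least 2-fold), and in 4888 with a block for each pair of Col-0 and N14 pools. Camera's adjusted p was 0.0048 for the flavonoid list (median -0.72), 0.049 for the lipid transfer list (median -0.66), 2.4e-05 for the flowering list (median -1.35) and 1.3e-06 for the floral list (median -3.13), and with an estimated correlation the adjusted p was 0.73, 0.13, 0.023 and 0.0036. With the experiment as a block the lipid transfer list had an adjusted p of 0.058, and with the pair block one of 0.085. With the pair block the floral list had an adjusted p of 0.073 with an estimated correlation, and the salicylate list lay lower (median -0.64, camera's adjusted p = 0.038, 0.69 with an estimated correlation).

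The difference between accessions in the response to priming was tested as an interaction. DEG14 [AT5G27660], a protease gene, had the largest positive difference (4.34 ± 0.30), since its level went from 3.98 to 16.6 CPM in N14 and from 60.5 to 12.4 CPM in Col-0. AT1G20030 (2.60 ± 0.53), AT2G21130 (2.11 ± 0.39), DI21 [AT4G15910] (1.90 ± 0.33) and AT3G07320 (1.36 ± 0.18) followed. HPL1 [AT4G15440], a hydroperoxide lyase gene, had the largest negative difference (-3.87 ± 0.49), going from 202 to 5.89 CPM in N14 and from 7.17 to 3.06 in Col-0, followed by the defence genes LURP1 [AT2G14560] (-3.08 ± 0.63) and ACD6 [AT4G14400] (-2.92 ± 0.44, 28.3 to 11.5 CPM in N14 and 80.5 to 248 in Col-0), KIN1 (-2.93 ± 0.57) and the chloride channel gene CLC-B [AT3G27170] (-2.23 ± 0.32). The interaction called 61 genes, 21 with a positive and 40 with a negative difference, N14 minus Col-0 (16 and 35 by at least 2-fold), and 1436 genes had an unadjusted p under 0.05. DESeq2 called 179, the groups of the comparison fitted alone 19 and the pair block 527. The COR (median -0.49, camera's adjusted p = 0.047), light-harvesting (-0.27, 0.017) and salicylate (-0.83, 8.6e-04) lists lay lower, each with an adjusted p of 0.84 with an estimated correlation, and with the experiment as a block the COR list had an adjusted p of 0.074. The count was 27 without the primed Col-0 pool of experiment 2, and the calls of KIN1 (in 4 of the other tables), LURP1 and AT1G20030 (without any of several pools) were not stable.

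The other interactions called no gene by edgeR's adjusted test. The difference in what remained after the lag had 622 genes at an unadjusted p under 0.05 and 3 by DESeq2, the difference in second against first cold 218 and 3, and the difference in age 843 and 10. The flavonoid (median -0.57, camera's adjusted p = 2.5e-04), jasmonate (-0.62, 0.0016) and heat shock (-1.32, 7.6e-05) lists differed after the lag, with adjusted p of 0.78, 0.47 and 0.20 with an estimated correlation. The heat shock median after the lag was lower in N14 in experiments 1 and 2 (-0.957 and -0.213, against 1.398 and 0.323 in Col-0). In experiment 3 it was higher in N14 (-0.393 against -0.495). The salicylate list differed between second and first cold (-0.79, 2.0e-07), with an adjusted p of 0.18 with an estimated correlation. With age the heat shock (1.34, 0.0054), flowering (-0.23, 9.9e-04) and floral (-3.59, 1.0e-19) lists differed, with adjusted p of 0.36, 0.094 and 1.2e-06 with an estimated correlation, and 5 floral markers were lower adjusted over the list alone. No floral marker had a mean above 0.582 CPM in N14 at 35 days. With a block for each pair of Col-0 and N14 pools, 1 gene was called in the difference after the lag, 2 in that of the second cold and 7 in that of age. With that block camera's test was also passed by the starch (-0.16, 0.019) and root (-2.37, 0.032) lists after the lag and by the cell wall (-0.33, 0.0037) and salicylate (-0.34, 0.028) lists with age, with adjusted p of 0.79, 0.25, 0.59 and 0.77 with an estimated correlation. With the experiment as a block the difference in age called 3 genes, and 1 gene was called without the 35-day N14 pool of experiment 1.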

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

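The difference between accessions in the change with age, the splits that part all pairs of pools and the tests of the floral markers and of the genes higher in N14 were chosen after the results had been seen, while the other splits of the libraries and the test of the genes lower in N14 were set out beforehand. The splits under the pair block were added after the real counts had been seen and set out before those of the splits were known. The results here are differences between the accessions in a response, each tested as an interaction.

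Priming acted differently on 61 genes in N14 and Col-0, and 2 of the 35 splits of the 12 libraries called as many, with 220 in the highest other split. These splits did not exclude chance, but they moved pools without regard to the pairs of Col-0 and N14 pools of the same condition and experiment. The split with 220 genes parted 4 of the 6 pairs, while 5 splits, the real one included, parted all 6 and called 61 in the real and 0 in the highest other split. With a block for each pair, 527 genes differed, and 46 in the highest other of the 10 splits that kept the pairs together. Both sets are too few for a share under 0.05. DEG14 had the largest difference (4.34), followed by AT1G20030 (2.60), AT2G21130 (2.11), DI21 (1.90) and AT3G07320 (1.36) on the positive side. HPL1 (-3.87), LURP1 (-3.08), KIN1 (-2.93), ACD6 (-2.92) and CLC-B (-2.23) had the largest negative differences, N14 minus Col-0. The split with 220 genes placed primed pools of both accessions from experiment 1 on the same side, together with the Col-0 pool of experiment 2, which points to a structure of the samples by experiment. As lists, the COR effectors (median -0.49), the light-harvesting and Rubisco genes (-0.27) and the salicylate genes (-0.83) differed in priming at camera's preset correlation and not with an estimated correlation, where the adjusted p was 0.84 for each, or 0.67 with the pair block. Without the control N14 pool of experiment 1, which had the highest PR1 level among the 28-day controls (86.8 CPM), the salicylate list had a median of -0.50 and camera's adjusted p was 0.19.

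After the lag the flavonoid list (-0.57), the jasmonate list (-0.62) and the heat shock list (-1.32) differed between accessions, in second against first cold the salicylate list (-0.79), and with age the heat shock list (1.34) and the flowering list (-0.23), none of which held with an estimated correlation. The heat shock differences shared the 35-day N14 pool of experiment 1, in which HSP70 stood at 99.8 CPM and the root marker PYK10 at 85.1 CPM against 16.3 and 19.2 in the other 35-day N14 pools. Without that pool the heat shock list had an adjusted p of 0.42 in the difference with age and 0.037 in that after the lag. The lag pools of experiment 1 also entered the difference after the lag. Their HSP70 level was 51.4 CPM in N14 and 34.6 in Col-0, with PYK10 at 13.5 and 33.8 CPM. By experiment the heat shock median after the lag was 1.398, 0.323 and -0.495 in Col-0 and -0.957, -0.213 and -0.393 in N14. The gap between accessions was thus widest in experiment 1, and its direction turned in experiment 3. No gene was called in these 3 interactions by edgeR's adjusted test, so that each of the 35 splits gave as many by construction and says nothing about chance. The highest other split called 638, 0 and 629 genes for the lag, the second cold and age, and the first and last of these point to a structure of the samples.

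The floral organ markers differed most as a list (median -3.59 with age, adjusted p = 1.2e-06 with an estimated correlation), since they rose in Col-0 between 28 and 35 days and not in N14, where the number of rosettes changed from 15 to 4 in the same way. With the pair block its adjusted p was 0.0044 with an estimated correlation. Flower tissue carried into single Col-0 pools was argued against, because 12 of the 12 Col-0 pools taken at 35 days or later lay above every 28-day pool. The counting method was argued against as well, because the median difference stayed at -3.56 or beyond in the other 6 tables. A loss of N14 reads on the Col-0 reference cannot be told apart from an absence of expression, because only 1 marker had a mean of at least 10 counts per library in both accessions at 35 days. An earlier transition to flowering in Col-0 may be the biological explanation, in line with FLC at 152 CPM in N14 and 5.57 CPM in Col-0, and remains an untested hypothesis.

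Of the genes called between the naive accessions, at any size of change, 597 were called higher and 802 lower in N14 in triggered plants as well and 17 the opposite way, against 70.4 and 105 for independent lists. Loss of N14 reads on the Col-0 reference lowers N14 values, so by its direction alone it does not account for the genes higher in N14. Their share, 45.5% of the genes at least 2-fold apart between the naive accessions, is therefore no further evidence. N14 reads placed on a near copy could raise that copy, which was not tested. Of the genes at least 2-fold apart, 450 of 670 higher and 567 of 804 lower in N14 were called that way by all 6 other counting methods. For the genes at least 2-fold lower in N14 a loss of reads stays open: a fixed loss gives the same difference in each condition, and 9.58% of them differed by less than 0.5 log2 units in triggered plants, against 21.9% of the genes at least 2-fold higher. Other evidence for sequence or gene content differences was limited to 9 genes with at most 3 counts in every N14 library and at least 5 CPM in Col-0 in the STAR table, among them AT5G36930 at 11.5 ± 1.82 CPM (mean ± SD over the 18 Col-0 libraries), and 2 genes the other way, such as AT2G07750 at 10.2 ± 5.75 CPM (over the 18 N14 libraries). The number depends on the table, since AT1G25211 reached 14, AT1G50290 25, AT2G09795 9 and AT3G27990 5 counts in an N14 library with CLC, AT1G25211 also 7 to 12 with BWA, kallisto, RSEM and Salmon, and AT2G07750 4 counts in a Col-0 library with kallisto and Salmon. A difference in expression between the accessions may account for these genes as well and was not tested apart from lost reads.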

How the results depend on the processing

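The fit with a block for each pair of Col-0 and N14 pools and the difference between accessions with age were added after the data had been seen, and all other alternatives were planned. Counts of called genes stayed within 1.5 times of the values above in 272 of 336 alternative fits over 18 contrasts. The calls of named genes, and the directions of those called in the fit used above, were kept in 26023 of 26639. A gene called in neither fit counted as kept even where its direction turned. Only genes called in the fit used above could therefore count as reversed. List calls were kept in 740 of 756, a total that holds no fit without a single library or with the compared groups alone. Where lists were refitted without a control N14 pool of experiment 1, some calls were lost, such as the heat shock list of the first cold in N14 (0.079). With other settings the cause was not tested. DESeq2 called 4 genes in memory of Col-0, 61 in memory of N14, 3 and 213 in second against first cold of Col-0 and N14, 1184 and 139 in age of Col-0 and N14, and 179, 3, 3 and 10 in the differences between accessions in priming, memory, second cold and age. The groups of a comparison fitted alone, with fewer samples, gave 1 and 532 genes in second against first cold of Col-0 and N14, 22 and 0 in age of Col-0 and N14, 1268 between naive accessions and 19 in the difference in priming. With no filter on low counts, age called 439 genes in Col-0, 19 in N14 and 2 in their difference. With the replicate number as a block, second against first cold of N14 called 5 genes, age of N14 12 and the difference in age 3, the lipid transfer list between triggered accessions had an adjusted p of 0.058 and the COR list in the difference in priming one of 0.074, and the other 15 counts stayed within 1.5 times and the other list calls were kept. The accession pair block called 4377 genes between naive and 4888 between triggered accessions, and 527, 1, 2 and 7 in the differences in priming, memory, second cold and age, and the lipid transfer list between triggered accessions had an adjusted p of 0.085 with it. In second against first cold of N14 the BWA table gave 6 genes and RSEM 0, and in age of N14 TopHat gave 1 and BWA, CLC, kallisto, RSEM and Salmon 0. List calls lost in other tables were the starch list (0.053 in BWA), jasmonate list (0.050 in TopHat, 0.062 in BWA) and heat shock list (0.072 in BWA) of the first cold in N14, the heat shock list after the lag in N14 (0.61 in BWA) and in the difference with age (0.27 in BWA), the lipid transfer list between triggered accessions (0.062 in TopHat and BWA, 0.056 in RSEM), and the COR list in the difference in priming (0.076 in TopHat, 0.23 in CLC, 0.15 in kallisto, 0.092 in Salmon). Reversed genes were KIN1 in accession naive with CLC (-0.74), kallisto (-0.76) and Salmon (-0.84), EDS5 in accession triggered with Salmon (0.071), and SAG12 in triggering Col-0 without the lag pool of experiment 2 (4.87, with a range from -4.21 to 4.87 over single pools left out). Without single libraries the counts ranged from 9715 to 10528 in priming Col-0, 8832 to 10430 in first cold of Col-0 at 35 days, 6431 to 7877 in triggering Col-0, 9590 to 11121 in priming N14, 9422 to 11217 in first cold of N14 and 7833 to 8568 in triggering N14. They ranged from 0 to 1 in memory Col-0, 0 to 179 in memory N14, 0 to 177 in second against first cold N14, 62 to 1479 in age Col-0, 0 to 359 in age N14, 1906 to 2410 between naive and 2139 to 2286 between triggered accessions, 27 to 89 in the difference in priming and 0 to 1 in that in age. Depth separated the groups of some comparisons. In age, memory and first cold at 35 days of Col-0, every 35-day control library had more counts than every library of the other group. In triggering N14, every triggered library had more counts than every lag library. Libraries were scaled for depth, and what these differences did to the calls was not tested. Genes near the floor of 3 counts, such as the floral markers of N14, have folds that the counts cannot settle.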

Other observations

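The tests of gene families and of the second cold by experiment were chosen after the results had been seen, while the test of a shared change after the lag was set out beforehand. Among 40 gene families taken from product names, SAUR genes, small auxin-induced transcripts tied to cell expansion, fell in 40 of 61 tested cases with priming of Col-0 (median -2.46) and in 43 with priming of N14 (median -2.69), and none rose. Among the called SAUR genes with a mean log2 CPM of at least 3, the largest changes in Col-0 were AT5G18030 (-5.37 ± 0.59), AT4G38840 (-2.70 ± 0.25) and AT4G38860 (-2.53 ± 0.28). Aquaporins, water channels of the plasma membrane and vacuole, fell in 14 of 24 cases in Col-0 and 17 in N14, with TIP2 at -3.06 ± 0.29 and PIP2B at -2.68 ± 0.30 in Col-0, and 1 rose in each. RNA helicase genes rose in 51 of 68 cases in Col-0 and 52 in N14, with AT4G16630 at 2.45 ± 0.30, and 5 and 8 fell. Proteasome subunit genes rose in 26 of 34 cases in Col-0 and 22 in N14, and genes of pentatricopeptide repeat proteins, which act on organelle RNA, in 136 and 161 of 242. By camera all of these passed at the preset correlation in both accessions, and none did with an estimated correlation, where the adjusted p in Col-0 was 0.23 for SAUR genes and aquaporins, 0.42 for helicases, 0.20 for proteasome subunits and 0.47 for pentatricopeptide repeat genes.

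Between the naive accessions the TIR-NBS-LRR genes, immune receptors, were lower in N14 in 26 of 67 cases and higher in 8 (median -0.40, adjusted p = 1.9e-07 and 0.99 with an estimated correlation). A loss of N14 reads on the Col-0 reference was not tested for this family and cannot be told apart from lower expression. With age in Col-0, 23 of 242 pentatricopeptide repeat genes fell and none rose (median -0.52, adjusted p = 4.2e-22 and 0.36 with an estimated correlation).

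The change between second and first cold in N14 comprised 532 genes when those 6 libraries were fitted alone, 124 higher and 408 lower, and 522 of them went the same way in Col-0 (r = 0.90 across these selected genes, which are not independent). Over all 20263 genes the changes of the accessions correlated by 0.39, and single experiments by a mean of 0.43 within the same experiment and 0.22 between different ones. SLAH3, an anion channel gene, ERD5, a proline dehydrogenase gene, and IP5PII were among the lower and CBF3, EXPA1 and RGF9 among the higher genes. On a score with a mean of 0 for the first cold at 35 days and 1 for the second cold, the primed pool of experiment 1, which had no earlier cold, reached 1.08 in N14 and 1.42 in Col-0, and those of experiments 2 and 3 stood at 0.09 and 0.04 in N14 and -0.08 and 0.05 in Col-0. The pools of the first cold at 35 days lay between -0.13 and 0.18 and those of the second cold between 0.55 and 1.26, each over 3 experiments and both accessions. That gap is set in part by construction, since the 6 N14 pools chose the genes and these groups set the scale in each accession. Only the primed pools took no part in either step. A difference between single experiments of a cold condition, shared by both accessions, is a candidate explanation, since primed pools spanned a range of at least 1.05 between experiments. The primed pools of experiment 1 reached this profile in both accessions with no earlier cold, which argues against a response that always needs a preceding cold treatment. They came from a single experiment, and the second highest primed pool stood at 0.047 in Col-0, the lower of the accessions. A contribution of preceding cold therefore stays open. SLAH3 stood at 5.21 CPM in the primed Col-0 pool of experiment 1 and at 163 and 149 CPM in those of experiments 2 and 3, and what differed between the experiments, such as the time of harvest, is not recorded in the labels.

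A lasting effect of the first cold would make the changes after the lag correlate between the accessions whichever experiment they come from. The correlation across genes averaged -0.10 for Col-0 and N14 changes from different experiments (range -0.24 to 0.08) and 0.31 for those of the same experiment (range 0.18 to 0.44), which argues against a shared change of that kind across all genes. The COR list went the other way, since its median was higher after the lag in all 3 experiments of both accessions (0.14, 0.21 and 0.93 in Col-0, and 1.14, 0.23 and 0.59 in N14), so that a remainder of the first cold in a limited group of genes stays open. Age cannot be told apart from such a remainder, since plants after the lag were 3 days older than the controls. The COR list also lay higher in 35-day than in 28-day controls. COR15A stood at 149 ± 60.0 and 237 ± 126 CPM in the 28- and 35-day controls of Col-0, and at 285 ± 155 and 442 ± 148 CPM in those of N14. For priming the correlations over all genes averaged 0.77 between different experiments and 0.83 within the same experiment. In the memory comparison the highest of the other splits of 6 libraries called 1187 genes in Col-0 and 1080 in N14 against 0 for the real one, and both placed the lag pools of experiments 1 and 3 with the control pool of experiment 3, which points to a structure of the samples shared by the accessions.

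With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split and the highest other split called 11082 and 1 genes in priming Col-0, 11501 and 1 in priming N14, 10503 and 0 in the first cold of Col-0 at 35 days, 10946 and 6 in that of N14, 8149 and 0 in triggering Col-0 and 9450 and 1 in triggering N14. They called 0 and 0 in second against first cold of Col-0, 1 and 0 in that of N14, 2501 and 265 between naive and 2827 and 0 between triggered accessions. In age they called 690 and 675 in Col-0 and 4 and 4676 in N14, where 2 splits gave as many and the highest placed the 35-day pools of experiments 1 and 2 with the 28-day pool of experiment 1, again a structure of the samples and not of age.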
